A study of Homo sapiens with 10 samples.

How the data were processed

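Single-cell RNA-seq had been done on 10 libraries of cells derived from the HES2 line, 1 library for each of 10 groups of lineage and day, made with 10x Genomics 3-prime version 3 chemistry. Each library was represented by 1 matrix of 33538 genes by cell barcodes. The deposited matrices held counts, that is, whole numbers of UMIs per gene and barcode, with no normalization. Per the file headers, the matrices had been made with Cell Ranger 3.1.0 for both aSHF libraries and 3.0.1 for the other 8, and the submitters' processing notes named the GRCh38 build. The groups were taken from the sample labels. In total 33456 of the 33538 gene IDs, 99.8%, were found in GENCODE 29, from which the coordinates were taken. In that annotation 2915 genes had exons that overlapped another gene on the same strand.

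The libraries held 2672 and 5228 barcodes at day 3 (FHF and SHF), 4108 and 8606 at day 4, 3146, 3241 and 3231 at day 6 (FHF, aSHF and pSHF) and 2352, 2909 and 3535 at day 20. Barcodes with at least 500 detected genes and at most 30% mitochondrial UMIs were used, and those with the highest doublet scores (Scrublet method in scanpy) were removed, at 0.8% per 1000 barcodes. This removed 55 and 210 barcodes at day 3, 132 and 573 at day 4, 78, 82 and 81 at day 6 and 40, 66 and 78 at day 20. The kept cells held 38841848 and 94887974 UMIs at day 3, 35282776 and 78248605 at day 4, 54175687, 51964194 and 41763307 at day 6 and 38898039, 37029371 and 34468064 at day 20. At these depths a count of 0, taken as at most 3 UMIs, allowed a level of 0.0316 CPM in the deepest library and 0.0870 CPM in the shallowest.

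UMIs were summed over the kept cells of each library and divided by their total to give counts per 1000000 UMIs (CPM). For each of 8 comparisons of lineages, 8 of successive stages and 3 within cardiomyocyte-like cells at day 20, a gene was counted when it reached 20 CPM in the higher library and the ratio of CPM + 1 was at least 2. Folds are ratios of CPM without a pseudocount, with exact conditional (Clopper-Pearson) 95% intervals, and shares of cells have exact 95% binomial intervals. With 1 library per group, no p-value was computed. For 30 gene lists the median log2 ratio of CPM + 1 was taken over members that reached 5 CPM in either library, and was placed among 10000 random lists of the same size matched on mean CPM. Overlaps between comparisons were counted among genes that reached 20 CPM in either library of both comparisons and set beside n1 × n2 / N, where n1 and n2 are the genes counted in each and N the genes measured in both. For comparisons that shared a library, libraries without an effect were simulated as well, but these held no variation between cultures.

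The libraries of each day were clustered together without integration (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5, seed 1). Clusters were named from 19 marker classes. A name needed 3 markers of its class among the 30 leading genes by fold, or 2 among the leading 10, together with 3 markers at 20 CPM and more markers than any other class. The folds were taken against the kept cells of all days. The cardiomyocyte-like name needed 8 of 15 markers at 100 CPM, a geometric mean of 150 CPM and no other class with more markers among the leading 10. A cluster whose median UMIs lay below its samples' median divided by 3 kept a name only with a marker among the leading 10. These thresholds for naming clusters were set after the clusters were seen. The groups, comparisons, cell filters, gene lists, marker classes, naming rule for genes and all but 3 of the alternatives were fixed before the data were examined. Clusters were not used to report their own leading genes as results.

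The genes named for each comparison were chosen by rule. For lineages and cardiomyocyte-like cells these were the 10 genes with the largest ratio of CPM + 1 in each direction among those at 20 CPM in the higher library, and for stages the 5 largest. From each described list the 2 to 4 members with the largest ratio were added. Mitochondrially encoded genes, ribosomal protein genes, genes of X inactivation, Y-linked genes and loci with only a clone name were left out. Of the genes so chosen, those not needed to describe a comparison were not printed. Some genes that the rule named are not reported here.

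The procedure was tested on simulated data with known changes, for day 3 FHF against SHF, day 20 pSHF against FHF, and the latter within cardiomyocyte-like cells. In each, 67 genes were set to 1.5-fold, 67 to 2.5-fold and 66 to 4-fold. Of the 1.5-fold genes 0 were counted, and 100% of the 2.5-fold and 4-fold genes were, with 0 in the wrong direction. Of the unchanged genes, 0 of 5462, 0 of 5892 and 0 of 5775 were counted, and the ratio intervals covered the true ratio for 95.3%, 95.1% and 95.5% of genes. A list of 15 genes set to 2.5-fold had medians of 1.30, 1.31 and 1.30 (percentile 100 in each), and an unchanged list of 15 had percentiles of 17.0, 12.8 and 59.1. The simulation contained no variation between replicate cultures, so it says nothing about that.

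The alternatives were TMM scaling (edgeR 4.0.16) and median of ratios scaling (DESeq2 1.42.0), totals without mitochondrial and ribosomal protein genes, and the mean of each cell's own CPM. Others were pseudocounts of 0.1 and 5, no minimum CPM and a minimum of 50, no filter on cells, a stricter filter (1500 genes and 15% mitochondrial UMIs), predicted doublets kept, Leiden resolutions of 0.25 and 1.0, and 15 principal components. After the data were seen 3 were added: cluster 10 of day 20 counted as cardiomyocyte-like, genes that overlap another gene left out, and cells of other types (endoderm-like, endothelial-like, blood-like, neural-like and amnion-like or surface-ectoderm-like) left out in the 8 comparisons of lineages. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3. Reads were not analysed here, and free RNA in the droplets was not corrected for.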

Results

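Single-cell RNA sequencing was carried out on cells derived from HES2, an established human embryonic stem cell line, that had been directed towards the heart fields of the embryo. The first heart field (FHF) contributes chiefly to the left ventricle, the anterior second heart field (aSHF) to the right ventricle and outflow tract, and the posterior second heart field (pSHF) to the atria and inflow region. There were 10 libraries, 1 per group, made with 10x Genomics version 3 chemistry: FHF and SHF mesoderm at day 3, FHF and SHF late mesoderm at day 4, FHF, aSHF and pSHF progenitors at day 6, and FHF, aSHF and pSHF cardiomyocytes at day 20. Per the labels, FHF mesoderm received 16 ng/mL BMP4, 5 ng/mL bFGF and 8 ng/mL Activin A, and SHF mesoderm received 3 ng/mL BMP4, 5 ng/mL bFGF and 1.5 ng/mL of a factor whose name is incomplete in the label. The WNT inhibitor IWP2 at 2 µM and VEGF at 10 ng/mL were given from day 3 to day 5. From day 5 to day 8, aSHF cultures received 2 µM retinol, the precursor of retinoic acid, with 10 ng/mL BMP4, and pSHF cultures received 2 µM retinol alone.

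The deposited matrices held 2352 to 8606 cell barcodes and 37633712 to 101939610 UMI counts per library. After the cell filters, the FHF and SHF libraries held 2507 and 4804 cells at day 3, with a median of 15061 and 19070.5 UMIs per cell, and 3892 and 7752 cells at day 4, with a median of 8373.5 and 9573 UMIs. At day 6 the FHF, aSHF and pSHF libraries held 3018, 3071 and 3051 cells, with a median of 16697.5, 15639 and 12567 UMIs. At day 20 they held 2091, 2786 and 2688 cells, with a median of 17597, 12763 and 12433 UMIs. UMIs were summed over the kept cells of each library and scaled to counts per 1000000 UMIs (CPM). A gene with no UMI in a library could still lie at up to 0.0316 to 0.0870 CPM, depending on the library.

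With 1 library per group, no difference has a replicate check and no p-value is given. Ranges in parentheses after a fold are exact 95% intervals that cover counting error only, and comparisons are between these libraries, not between conditions. Genes are counted as different when the ratio of CPM + 1 was at least 2 and the higher library reached 20 CPM. List members called higher or lower met both limits. A member called neither can lie beyond 2-fold where it stayed below 20 CPM in both libraries. Medians of gene lists are log2 ratios of CPM + 1 over members that reached 5 CPM in either library. Most are followed by their percentile among 10000 random lists of matched size and expression, which describes these libraries.

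**Figure D1:**
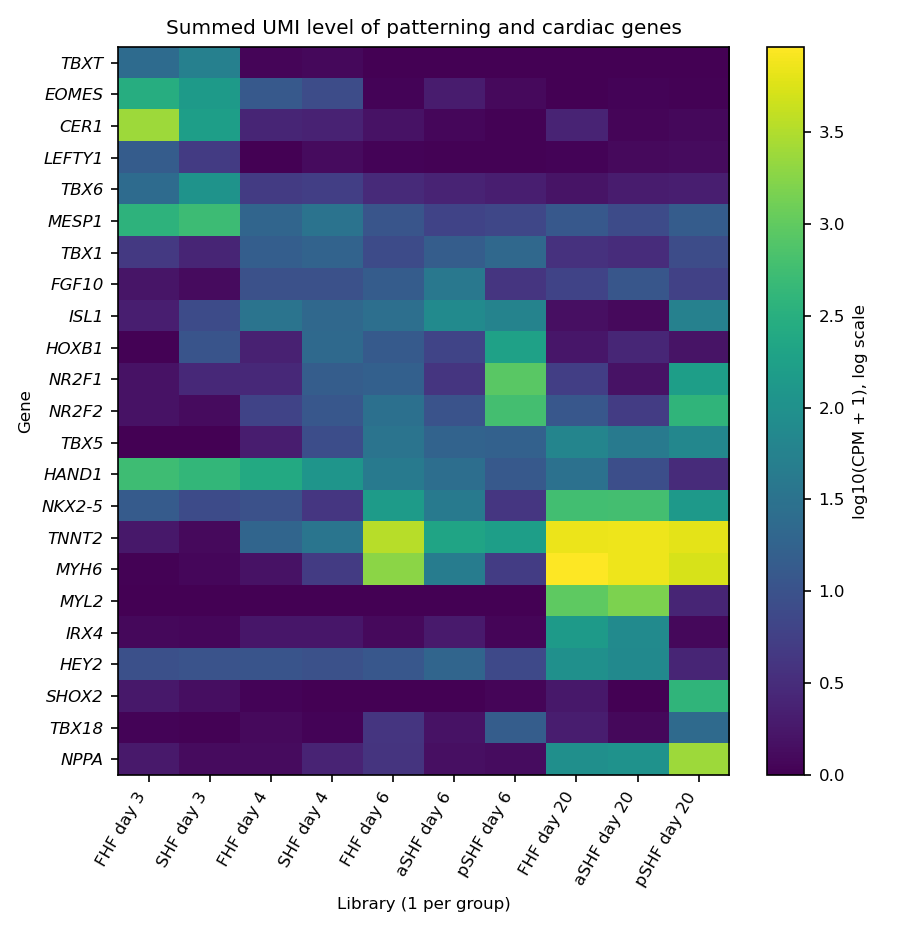
Heat map of the summed level, log10(CPM + 1), of 23 patterning and cardiac genes (vertical axis) in the 10 libraries (horizontal axis, 1 library per group). MYL2 is high in the FHF and aSHF cardiomyocyte libraries (957 and 1508 CPM) and low in pSHF (1.57 CPM), where SHOX2 and NPPA are high.

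The day 3 comparison asked how the mesoderm of the FHF and SHF protocols differed. Some genes of the primitive streak and of Nodal signalling were higher in the FHF library, and some genes of paraxial mesoderm were higher in the SHF library. CER1 (ENSG00000147869, GRCh38 chromosome 9, 14719724 to 14722717), which encodes a secreted Nodal and BMP antagonist, stood at 2391 CPM in FHF and 164 CPM in SHF, 14.6-fold higher (14.4 to 14.9). CYP26A1, the enzyme that degrades retinoic acid, was 18.4-fold higher in FHF (17.7 to 19.0), at 736 and 40.1 CPM. In the other direction, the homeobox genes MEIS2 and CDX2 were 42.5-fold (33.7 to 54.2) and 113-fold (61.6 to 237) higher in SHF. Of 5945 genes that reached 20 CPM in either library, 268 differed at least 2-fold, 157 higher in FHF and 111 higher in SHF. With no minimum CPM the split was 416 and 468.

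Among other genes with large ratios, ATP4B, a subunit of the gastric proton pump, was 59.1-fold higher in FHF (49.1 to 71.6), the neuregulin receptor ERBB4 44.8-fold (34.5 to 59.3) and the basement membrane gene FREM1 23.9-fold (23.0 to 24.9). ANKS1B (21.5-fold, 18.7 to 25.0) and PLSCR2 (17.0-fold, 15.6 to 18.7) followed. GYPE was 24.9-fold higher, a value that is uncertain because GYPE has near-identical paralogs. The largest ratios in SHF included PPP1R17 (46.1-fold, 36.7 to 58.8), CDX1 (61.0-fold, 37.5 to 107) and PCDH19 (11.9-fold, 11.0 to 13.0). They also included the WNT pathway genes RSPO3 (24.0-fold, 20.6 to 28.0), LEF1 (23.9-fold, 19.6 to 29.4) and DKK4 (13.8-fold, 10.6 to 18.2), the Notch ligand DLL1 (14.3-fold, 11.2 to 18.7) and LINGO1 (12.8-fold, 10.1 to 16.4).

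Of 11 measured primitive streak genes, 4 were at least 2-fold higher in FHF, 1 was higher in SHF and 6 were neither, with a median of 0.68 (percentile 100). LHX1 stood at 2063 CPM in FHF and 326 CPM in SHF and GSC at 77.9 and 11.6 CPM, whereas TBXT was 2.23-fold higher in SHF (2.08 to 2.40). Of 9 Nodal response genes, 4 were higher in FHF and 5 neither (median 1.55, percentile 100), and TDGF1, the Nodal co-receptor, was among them at 237 and 50.1 CPM. Of 8 paraxial mesoderm genes, 4 were higher in SHF and 4 neither (median -1.99, percentile 0), among them TBX6 at 23.7 CPM in FHF and 106 CPM in SHF and DLL3 at 93.1 and 342 CPM. WNT response genes had a median of -0.72 (percentile 0), with 2 of 10 higher in SHF and DKK1, a WNT antagonist, higher in FHF at 259 and 46.7 CPM. The 13 BMP response genes had a median of -0.51 (percentile 0): 3 were higher in SHF, including MSX1 at 23.5 and 143 CPM and ID3 at 235 and 561 CPM, 1 was higher in FHF and 9 were neither. The posterior second heart field list stood lowest, at -3.20 over 6 members (percentile 0, and -3.14 with an undetected member at its bound). Of these, 2, MEIS2 and MEIS1, were counted as higher in SHF, since the count also needs 20 CPM. Of 8 endoderm genes, 4 were higher in FHF and 4 neither (median 0.65, percentile 100), with HHEX 7.68-fold (6.97 to 8.47) and APOA2 6.03-fold (5.58 to 6.53) higher. Endoderm-like clusters held 9.41% of FHF cells (exact 95% interval 8.30 to 10.6) and 6.68% of SHF cells (5.99 to 7.43).

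At day 4 the comparison asked how the libraries differed within the IWP2 and VEGF treatment, which both cultures received from day 3 to day 5. Fewer genes differed than between the day 3 libraries, 112 of 6000, with 54 higher in FHF and 58 higher in SHF. The split was 23 and 21 at a minimum of 50 CPM and 55 and 51 with cells of other types left out. CHGA (ENSG00000100604, chromosome 14, 92923080 to 92935293), which encodes chromogranin A, was 20.5-fold higher in FHF (17.8 to 23.6), at 57.6 and 2.81 CPM, and BMP4 was 3.37-fold higher (3.20 to 3.55), at 104.98 and 31.1 CPM. In SHF, HOXB1 (ENSG00000120094, chromosome 17, 48528526 to 48531001), an anterior HOX gene induced by retinoic acid, was 16.8-fold higher (12.5 to 23.1), at 1.28 CPM in FHF and 21.4 CPM in SHF. The heart field factor HAND1 was higher in FHF (252 and 114 CPM), and MEF2C, a myogenic transcription factor, was higher in SHF (8.81 and 29.7 CPM).

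Other large ratios in FHF at day 4 were those of the chemokine CXCL14 (6.01-fold, 5.50 to 6.57), the apolipoprotein APOA1 (5.79-fold, 5.27 to 6.38), NGEF (5.05-fold, 4.49 to 5.69) and HS6ST2 (4.88-fold, 4.38 to 5.43). SPOCK3, PPP1R1B and CPE were 4.58-fold, 4.11-fold and 3.34-fold higher, and GYPB, whose paralogs are near-identical, 4.42-fold. In SHF they were those of RGS13 (30.7-fold, 21.7 to 45.0), PANX2 (13.7-fold, 11.1 to 17.3), DGKI (11.5-fold, 9.20 to 14.7) and PCP4 (10.4-fold, 8.82 to 12.2). The collagen gene COL3A1 (9.26-fold, 7.37 to 11.8), BAALC (8.99-fold, 7.68 to 10.6), the natriuretic peptide gene NPPB (7.03-fold, 5.86 to 8.51), NMU (6.84-fold, 6.28 to 7.47) and SOST (5.31-fold, 4.82 to 5.85) completed the 10.

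The retinoid response list lay lower in FHF at day 4, with a median of -0.998 over 9 members (percentile 0). The retinoic acid binding protein gene CRABP1 stood at 10.4 and 47.2 CPM and the receptor gene RARB at 8.47 and 21.0 CPM, and 7 members were neither. Of 7 posterior second heart field genes, HOXB1 and MEIS2 were higher in SHF and 5 were neither (median -1.29, percentile 0). The BMP response list had the opposite sign to day 3, with a median of 0.62 over 13 members (percentile 100). Of these, 1 member, HAND1, was counted as higher in FHF and 12 were neither. Of 12 vascular genes, 3 were higher in SHF and 9 neither (median -0.83, percentile 0): PLVAP at 17.1 and 53.4 CPM, CDH5 at 13.2 and 38.5 CPM and TEK at 7.45 and 20.4 CPM. Endothelial-like clusters held 8.07% of FHF cells (7.23 to 8.97) and 17.8% of SHF cells (17.0 to 18.7); at a Leiden resolution of 1.0 no day 4 cluster received that name in either library. Among genes that reached 20 CPM in either library on both days, 15 were higher in FHF at day 3 and day 4, against 0.376 for independent lists, and 9 were higher in SHF on both days, against 0.269. These numbers were 8 and 2 at a minimum of 50 CPM.

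The day 6 comparisons asked how the progenitors of the FHF, aSHF and pSHF protocols differed. Against FHF, the aSHF library had lower levels of contractile genes and higher levels of some anterior second heart field genes. MYH6 (ENSG00000197616, chromosome 14, 23381990 to 23408277), the alpha myosin heavy chain, stood at 45.5 CPM in aSHF and 1904 CPM in FHF, 41.8-fold lower (40.2 to 43.6), and the troponin gene TNNT2 at 203 and 3486 CPM, 17.2-fold lower (16.8 to 17.5). ISL1, a second heart field transcription factor, was 2.89-fold higher in aSHF (2.72 to 3.07), at 77.5 and 26.8 CPM, and FGF10, a growth factor of the anterior field, 2.80-fold higher (2.57 to 3.06). Of 6463 genes, 512 differed at least 2-fold, 214 higher in aSHF and 298 higher in FHF. The split was 384 and 287 when totals left out mitochondrial and ribosomal protein genes.

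The largest ratios in aSHF over FHF were those of the noncoding RNA LINC00458 (31.4-fold, 27.4 to 36.1), DKK1 (15.7-fold, 12.8 to 19.4) and LMLN2 (11.4-fold, 9.58 to 13.8). Other large ratios were those of TNFAIP3 (10.5-fold, 8.64 to 12.9), the FGF antagonist IL17RD (10.4-fold, 8.93 to 12.2), the cadherin CDH11 (9.84-fold, 9.13 to 10.6) and RGS2 (8.996-fold, 8.25 to 9.83). DACT1, part of whose exons overlap another gene, and PRDM1 were 7.55-fold and 7.11-fold higher. In FHF they were mostly muscle genes: SMPX (361-fold, 190.2 to 791), CSRP3 (347-fold, 168 to 865), TECRL (112-fold, 92.4 to 137), ASB2 (100.3-fold, 71.3 to 146), the calcium pump regulator PLN (76.7-fold, 65.0 to 91.0), TNNC1 (37.6-fold, 35.9 to 39.5) and MYL3 (36.9-fold, 32.2 to 42.5). The secreted protein gene CCDC80 was 64.9-fold higher in FHF (58.4 to 72.4), and the immediate early gene FOSB 44.3-fold (36.7 to 53.9).

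Of 16 sarcomere genes, 15 were at least 2-fold higher in FHF than in aSHF and 1 was neither (median -3.41, percentile 0). Of 10 calcium handling genes, 6 were higher in FHF and 4 neither (median -2.03, percentile 0), among them HRC at 3.00 CPM in aSHF and 55.7 CPM in FHF. Of 10 anterior second heart field genes, 4 were higher in aSHF and 6 neither (median 1.13, percentile 100); besides ISL1 and FGF10 these were PRDM1 at 38.9 and 5.46 CPM and the Notch ligand JAG1 at 263 and 98.4 CPM. The first heart field list had a median of -0.88 over 7 members (percentile 0.16), with NKX2-5 at 41.2 and 146 CPM. The posterior second heart field list, at -1.01 over 7 members (percentile 0.03), turned to 0.77 without mitochondrial and ribosomal protein genes in the totals; MEIS1 was 3.79-fold higher (3.62 to 3.96) and NR2F2 3.06-fold lower (2.76 to 3.40) in aSHF. Of 14 glycolysis and hypoxia genes, 8 were higher in FHF and 6 neither (median -1.29, percentile 0), with ENO1 at 631 CPM in aSHF and 2202 CPM in FHF. Of 11 endoderm genes, 5 were higher in FHF and 6 neither (median -2.03, percentile 0), with TTR at 3.50 and 74.9 CPM. Endoderm-like clusters held 4.94% of FHF cells (4.19 to 5.77) and 0.586% of aSHF cells (0.348 to 0.925). The aSHF files name another Cell Ranger version than the FHF and pSHF files, so in comparisons of aSHF with either of them the software and the lineage are confounded.

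Against FHF, the pSHF library at day 6 had higher levels of some genes of the posterior field and of the retinoic acid response. NR2F1 (ENSG00000175745, chromosome 5, 93583224 to 93594615) and NR2F2 (ENSG00000185551, chromosome 15, 96325938 to 96340263), nuclear receptors of the atrial programme, stood at 886 and 604 CPM in pSHF and 15.3 and 28.0 CPM in FHF, 57.9-fold (54.1 to 62.1) and 21.6-fold (20.5 to 22.7) higher. CYP26A1 (ENSG00000095596, chromosome 10, 93073475 to 93077890), a direct target of retinoic acid, was 72.6-fold higher (51.8 to 105.2) and HOXB1 14.9-fold higher (13.8 to 16.2). MYH6 was 468-fold lower in pSHF (402 to 547), at 4.07 CPM, and NKX2-5, a cardiac homeobox gene, 46.3-fold lower (39.0 to 55.5), at 3.16 and 146 CPM. Of 6568 genes, 604 differed, 241 higher in pSHF and 363 higher in FHF. Scaling by the median of ratios shifted all log2 ratios by -0.15, and by TMM by -0.12; the split by the median of ratios was 171 and 429.

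The noncoding RNA HOTAIRM1 of the HOXA cluster stood at 58.8 CPM in pSHF and had 3 UMIs in FHF, a ratio of 1061 (363 to 5149). IGFBP5 was 49.99-fold higher in pSHF (44.6 to 56.2), the neurotrophin gene BDNF 311-fold (121 to 1145), ITGA11 68.1-fold (43.4 to 114), LAMP5 34.2-fold (27.1 to 43.8) and KITLG 32.0-fold (26.0 to 39.9). The antisense RNA NR2F1-AS1 was 64.5-fold higher (48.9 to 86.8). In FHF the apolipoprotein gene APOA2 (1215-fold, 474 to 4461), TNNC1 (615-fold, 498 to 769), SMPX (523-fold, 224 to 1611), MYL3 (287-fold, 189.6 to 459), ACTC1 (139.7-fold, 133 to 147), NEBL (102-fold, 89.6 to 117), DGKI (88.2-fold, 71.5 to 110.1), the myocardin gene MYOCD (69.7-fold, 57.6 to 85.2) and MYL4 (54.1-fold, 51.8 to 56.5) had the largest ratios.

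Of 12 posterior second heart field genes, 4 were higher in pSHF and 8 neither (median 2.58, percentile 100; unchanged at 2.58 with 2 undetected members at their bounds), including MEIS2 at 626 CPM in pSHF and 159.8 CPM in FHF. Of 9 HOX genes, 5 genes of the HOXB cluster were higher in pSHF and 4 neither (median 1.78, percentile 100, and 1.78 with 3 members at their bounds). HOXB2 stood at 119 and 33.8 CPM and HOXB5 at 24.7 and 8.49 CPM. Of 9 retinoid response genes, 3 were higher in pSHF, 1 was higher in FHF and 5 were neither (median 0.99, percentile 100): RARB was 3.21-fold higher (2.95 to 3.50) and TGM2 2.70-fold lower (2.43 to 3.00). Of 16 sarcomere genes, 15 were higher in FHF and 1 neither (median -4.87, percentile 0). Of 13 BMP response genes, 5 were higher in FHF, 1 was higher in pSHF and 7 were neither (median -0.75, percentile 0), with BMPER at 6.68 and 78.4 CPM, BAMBI at 31.4 and 266 CPM and TBX2 at 48.3 and 16.1 CPM. Of 10 anterior second heart field genes, JAG1, MEF2C and HAND2 were higher in FHF, TBX1 and ISL1 were higher in pSHF and 5 were neither (median -1.55, percentile 0). No pSHF cell lay in an endoderm-like cluster, which allows a share of up to 0.121%.

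Between the 2 libraries labelled as treated with retinol, pSHF had the higher level of some retinoid response and posterior genes, and aSHF of some BMP response and anterior genes. The treatment of aSHF was taken from its label and was not checked otherwise. NR2F1 was 291-fold higher in pSHF (249 to 343), NR2F2 65.9-fold (60.2 to 72.4), CYP26A1 45.5-fold (34.6 to 61.2) and HOXB1 32.7-fold (29.1 to 36.9). HAS2 (ENSG00000170961, chromosome 8, 121612116 to 121641390), the hyaluronan synthase of the endocardial cushions, was 91.7-fold higher in aSHF (78.4 to 108), at 3.76 CPM in pSHF and 345 CPM in aSHF, and FGF10 12.1-fold higher (10.1 to 14.6). Of 6683 genes, 651 differed, 307 higher in pSHF and 344 higher in aSHF.

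Large ratios in pSHF over aSHF were also those of HOTAIRM1 (382-fold, 193 to 885), NR2F1-AS1 (121-fold, 82.6 to 186), NR2F2-AS1 (119.6-fold, 78.0 to 194), SHROOM3 (70.0-fold, 55.7 to 89.2), DUSP9 (51.2-fold, 39.0 to 68.6), BCO2 (39.0-fold, 32.0 to 48.1) and IGFBP5 (37.8-fold, 34.1 to 41.9). BCO2 overlaps another gene in part. In aSHF the others were APOA2 (289-fold, 113 to 1063), FYB2 (152-fold, 77.1 to 353), RGS4 (65.5-fold, 45.5 to 98.0), MYOCD (55.6-fold, 45.9 to 67.9), JAG1 (32.3-fold, 29.03 to 36.1), FBLN2 (30.4-fold, 24.8 to 37.7), LINC00458 (30.3-fold, 26.1 to 35.4), the myosin kinase MYLK3 (23.8-fold, 20.8 to 27.4) and BMPER (23.4-fold, 20.7 to 26.4).

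Of 8 retinoid response genes, 3 were higher in pSHF and 5 neither (median 1.16, percentile 100), with the retinol receptor gene STRA6 at 30.1 and 11.2 CPM. HOX genes had a median of 3.27 over 9 members (percentile 100, and 3.26 with 2 members at their bounds). HOXB1, HOXB4 and HOXB5 were counted as higher in pSHF. Of 14 BMP response genes, 6 were higher in aSHF, TBX2 was higher in pSHF and 7 were neither (median -1.36, percentile 0); SMAD6 stood at 7.06 and 50.6 CPM. Of 11 anterior second heart field genes, 5 were higher in aSHF and 6 neither (median -1.46, percentile 0), including PRDM1 at 5.70 and 38.9 CPM. Of 7 FGF response genes, 4 were higher in aSHF and 3 neither (median -1.25, percentile 0.01), with IL17RD and SPRY2 each 8.46-fold higher. Of 12 sarcomere genes, 6 were higher in aSHF and 6 neither (median -2.37, percentile 0). Extracellular matrix genes had a median of -0.95 (percentile 0), with FN1 at 91.2 CPM in pSHF and 705 CPM in aSHF and COL3A1 at 136 and 16.9 CPM.

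Cardiomyocyte-like clusters held 1105 of 3018 FHF cells at day 6, 36.6% (34.9 to 38.4). They held 1 of 3071 aSHF cells and 0 of 3051 pSHF cells, which allows a pSHF share of up to 0.121%. The rule for this name was set after the data were examined. Clusters 0 and 3 reached its marker threshold, with 8 markers at 100 CPM, but were left unnamed because 1 fibroblast marker and no cardiomyocyte marker was among their 10 leading genes. They held 27.3% and 22.0% of FHF cells, 0.0651% and 0.0326% of aSHF cells and 0% of pSHF cells. These clusters came almost wholly from 1 library, so they may stand for that library. Of the genes at 20 CPM in both comparisons with FHF at day 6, 178 were higher in FHF than in both aSHF and pSHF, against 17.6 for independent lists, and 30 were higher in both aSHF and pSHF than in FHF, against 2.40. Simulated libraries without an effect gave 0 in both directions, but they held counting error alone, so this value does not bear on the overlap. Part of the excess may come from the shared FHF library.

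**Figure D2:**
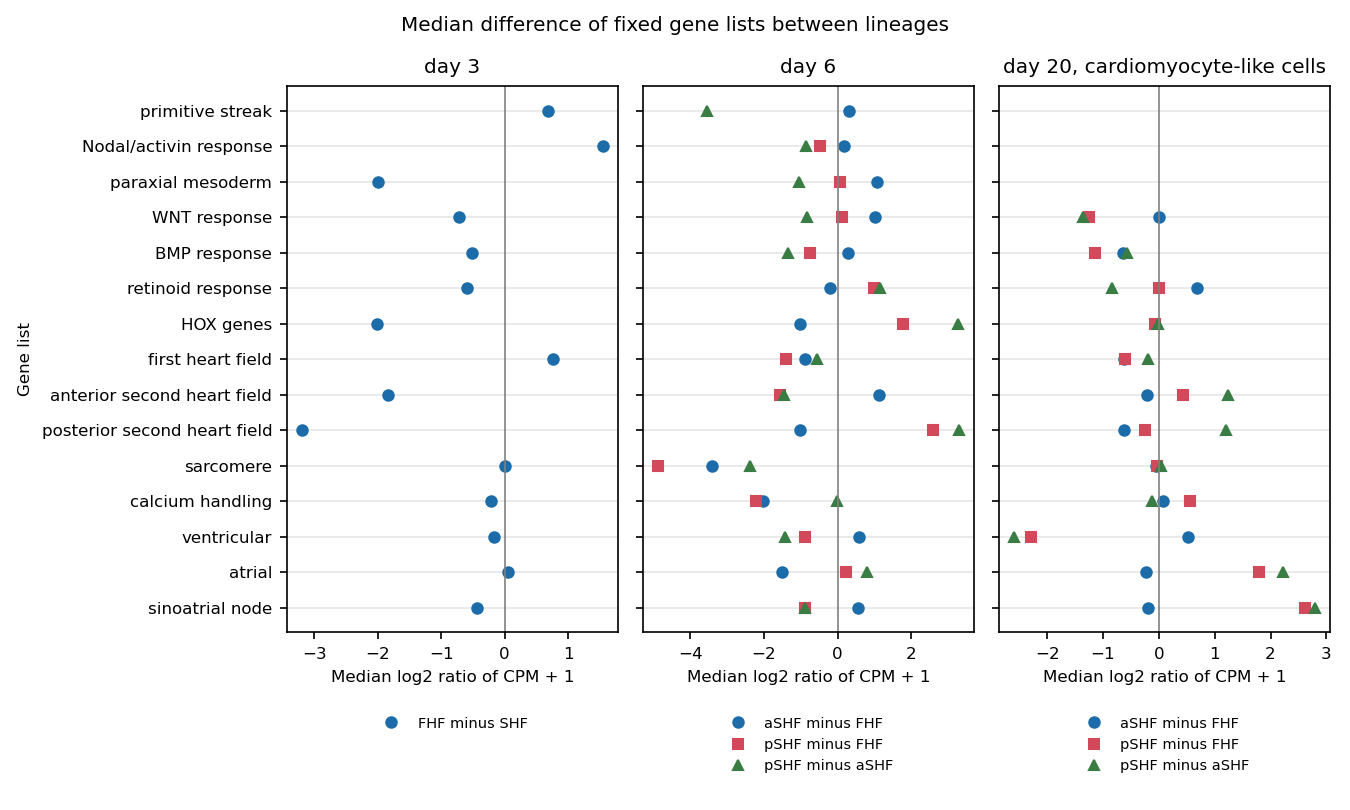
Median log2 ratio of CPM + 1 (horizontal axis) of 15 fixed gene lists (vertical axis) at day 3, at day 6 and in the cardiomyocyte-like cells of day 20; each point is 1 comparison of 2 libraries, and 0 marks equal levels. The sarcomere list lies at -3.41 and -4.87 for aSHF and pSHF against FHF at day 6 and at -0.05 and -0.03 at day 20, while the sinoatrial node list lies at 2.62 and 2.80 for pSHF against FHF and aSHF at day 20. Values of day 6 cover whole libraries. The day 20 cells were named by markers that include many sarcomere genes, so similar sarcomere levels there were partly set by that choice.

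At day 20 the comparisons asked which cardiomyocyte types the 3 lineages gave. The share of cardiomyocyte-like cells was 97.9% in FHF (2047 of 2091 cells, 97.2 to 98.5), 98.995% in aSHF (2758 of 2786, 98.6 to 99.3) and 56.8% in pSHF (1526 of 2688, 54.9 to 58.7). The pSHF share ran from 48.0% with the stricter cell filter to 71.4% with no cell filter. The rest of the pSHF library held 13.9% fibroblast-like (12.6 to 15.3), 6.03% endothelial-like (5.16 to 6.99), 3.35% endoderm-like (2.70 to 4.10) and 0.930% amnion-like or surface-ectoderm-like cells (0.603 to 1.37). Unnamed clusters held 19.0% (17.5 to 20.5). Among these, cluster 10 reached the cardiomyocyte marker level but had more smooth muscle markers among its leading genes; it held 12.1% of pSHF cells, 0.0478% of FHF cells and 0% of aSHF cells. Cluster 8 also reached that level, with 13 markers at 100 CPM, but was left unnamed for its median of 1322 UMIs per cell and the lack of a cardiomyocyte marker among its 10 leading genes. It held 6.96% of pSHF cells, so the pSHF share depends on these rules. Endothelial-like cells made up 1.48% of FHF and 0.503% of aSHF, and fibroblast-like cells 0.430% and 0.431%. Clusters that came mostly from 1 library may stand for that library and not for a cell type. Barcodes above 30% mitochondrial UMIs, which were left out, made up 19.4% of the pSHF library, 8.84% of FHF and 1.48% of aSHF.

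**Figure D3:**
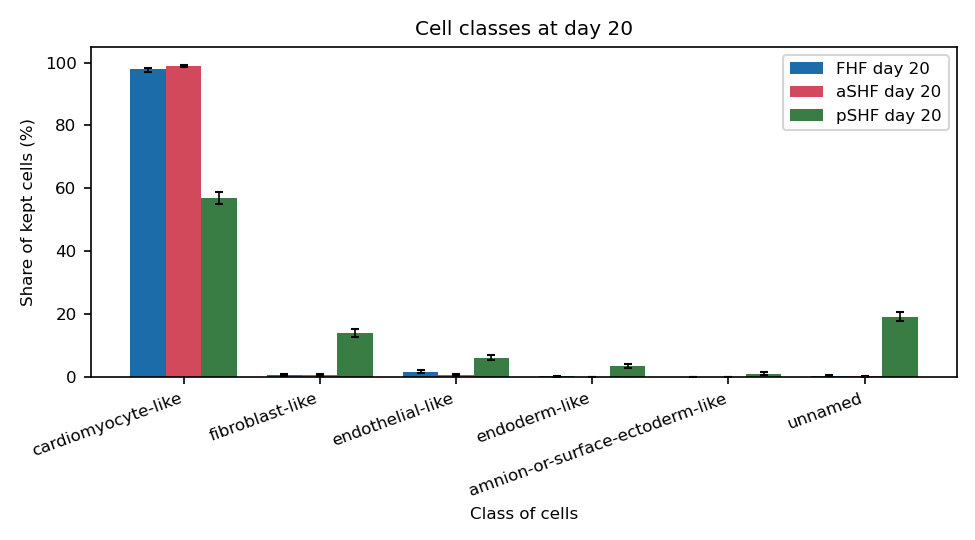
Share of kept cells in each class of clusters at day 20 (bars, percent), for the FHF, aSHF and pSHF libraries (1 library each); error bars are exact 95% binomial intervals and cover counting error only. The cardiomyocyte-like class holds 97.9%, 98.995% and 56.8% of the cells.

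The FHF and aSHF cardiomyocyte libraries differed in fewer genes than either did from pSHF, and both expressed ventricular genes. Of 6398 genes, 264 differed at least 2-fold, 169 higher in aSHF and 95 higher in FHF. The split was 170 and 155 when totals left out mitochondrial and ribosomal protein genes. It was 148 and 93 with genes that overlap another gene left out. The Cell Ranger version also differed between these libraries. HES1 (ENSG00000114315, chromosome 3, 194136145 to 194138732), a Notch target, was 17.1-fold higher in FHF (16.1 to 18.2), at 29.5 CPM in aSHF and 504 CPM in FHF, and HEY1, another Notch target, 10.9-fold higher (8.61 to 14.01). PLN was 2.86-fold higher in aSHF (2.81 to 2.90), at 1761 and 617 CPM, and the iron regulator gene HAMP 5.31-fold higher (5.09 to 5.55). The pacemaker channel gene HCN4 was 2.56-fold lower in aSHF (2.36 to 2.78), at 22.3 and 57.0 CPM.

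Other large ratios in aSHF were those of the RNA gene SNHG25 (9.84-fold, 8.21 to 11.9), the growth factor gene AREG (8.01-fold, 6.94 to 9.28), the VEGF receptor gene FLT1 (8.00-fold, 6.88 to 9.35), PCDH9 (7.48-fold, 6.86 to 8.17), SLC35F1 (7.06-fold, 6.02 to 8.33) and the homeobox gene IRX1 (6.57-fold, 5.98 to 7.22). IGFBP2 was 6.22-fold (6.00 to 6.45), CXCL12 5.64-fold (5.09 to 6.26) and C1QTNF4 5.46-fold (5.02 to 5.94) higher. In FHF they were those of LGALS3 (5.77-fold, 5.20 to 6.40), CLDN6 (5.60-fold, 5.02 to 6.27), TMEM88 (5.00-fold, 4.27 to 5.86), FBXL22 (4.90-fold, 4.38 to 5.49), AHNAK2 (4.26-fold, 3.76 to 4.84) and LIX1 (4.18-fold, 3.76 to 4.67). The histone genes HIST1H1B (11.7-fold) and HIST1H1A (4.63-fold) were also higher in FHF and are uncertain, as members of a family of near copies.

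The ventricular list had a median of 0.54 over 10 members (percentile 99.98), with PLN and FHL2 2-fold higher in aSHF and 8 neither. None of 18 sarcomere genes was counted as different (median -0.05, percentile 16.0). Of 7 first heart field genes, HCN4, HAND1 and CORIN were higher in FHF and 4 neither (median -0.62, percentile 0). Of 13 BMP response genes, 3 were higher in FHF and 10 neither (median -0.64, percentile 0), among them ID1 at 610.2 and 1392 CPM and ID2 at 175 and 401 CPM. Of 7 retinoid response genes, TGM2 was higher in aSHF and 6 neither (median 0.68, percentile 99.9). Of 15 cell cycle genes, 8 were higher in FHF and 7 neither (median -1.26, percentile 0), with MKI67 at 22.6 and 71.4 CPM. In the cardiomyocyte-like cells alone, 263 genes differed, 167 higher in aSHF and 96 in FHF, or 171 and 151 without mitochondrial and ribosomal protein genes. The ventricular median was 0.53 (percentile 99.9) and HES1 was 18.2-fold higher in FHF (17.1 to 19.4), with NPPB 5.17-fold higher (5.01 to 5.34), S100A11 5.91-fold lower (4.91 to 7.16) and S100A10 5.61-fold lower (4.74 to 6.67) in aSHF. FHF cells of this class lay mostly in cluster 0, aSHF cells in clusters 3 and 4 and pSHF cells in cluster 7.

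Against FHF and aSHF, the pSHF library at day 20 had higher levels of some atrial and sinoatrial node genes and lower levels of most ventricular genes, together with higher levels of some genes of fibroblasts and endoderm. MYL2 (ENSG00000111245, chromosome 12, 110910819 to 110920722), the ventricular myosin light chain, stood at 1.57 CPM in pSHF, 611-fold lower than in FHF (468 to 813) and 963-fold lower than in aSHF (738 to 1282). IRX4 (ENSG00000113430, chromosome 5, 1877413 to 1887236), a ventricular homeobox gene, was 616-fold (312 to 1427) and 336-fold (170.3 to 779) lower. SHOX2 (ENSG00000168779, chromosome 3, 158095954 to 158106503), a regulator of the sinoatrial node, stood at 388 CPM in pSHF, 487-fold above FHF (343 to 717). In aSHF SHOX2 had 1 UMI, a ratio of 14379 (2580 to 567965). NPPA (ENSG00000175206, chromosome 1, 11845709 to 11848345), the atrial natriuretic peptide gene, was 25.4-fold (24.6 to 26.2) and 22.7-fold (22.0 to 23.5) higher. Against FHF, 758 of 6581 genes differed, 411 higher in pSHF and 347 in FHF; against aSHF, 868 of 6582 differed, 400 higher in pSHF and 468 in aSHF. The split against FHF was 1543 and 656 with no minimum CPM, 194 and 198 at a minimum of 50 CPM, and 349 and 370 with cells of other types left out. Against aSHF it was 542 and 471 without mitochondrial and ribosomal protein genes, 628 and 525 with the stricter cell filter and 1556 and 888 with no minimum CPM.

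Among the largest ratios in pSHF over FHF were genes of liver and gut endoderm. AFP (alpha-fetoprotein) was 309-fold higher (252 to 383), FABP1 474-fold (287 to 847), FGB 238-fold (144 to 425), APOA2 205-fold (155 to 277) and SERPINA1 104-fold (87.0 to 126), while TTR had 2 and AGR2 1 UMI in FHF, ratios of 5140 (1422 to 42448) and 2954 (529.8 to 116740). The mesenchymal genes DLK1 (752-fold, 501 to 1186) and COL3A1 (63.6-fold, 55.0 to 74.0) were also among them. Over aSHF, AFP was at least 9020-fold, TTR at least 3262-fold and FGB at least 1131-fold higher, since aSHF had 0 UMIs. ALB was 2049-fold higher (1040 to 4748). In FHF and aSHF the largest ratios over pSHF included HEY2 (61.1-fold, 46.8 to 81.3, and 46.4-fold, 35.6 to 61.8), FBN2 (46.1-fold, 41.9 to 50.8, and 45.4-fold, 41.2 to 50.01) and MOXD1 (48.7-fold, 37.8 to 63.8, and 118-fold, 92.1 to 155). WNT2 (50.1-fold, 38.8 to 66.0) was among those of FHF, where GADL1 was at least 364-fold higher. Among those of aSHF were FGF18 (42.3-fold, 35.5 to 50.7), IRX1 (48.9-fold, 38.0 to 63.9), SCUBE3 (35.6-fold, 28.9 to 44.5) and the noncoding BANCR (68.1-fold, 48.4 to 99.2).

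Of 10 ventricular genes, 7 were higher in FHF than in pSHF and 3 neither (median -2.21, percentile 0), and 8 were higher in aSHF and 2 neither (median -2.40, percentile 0). Of 15 atrial genes, 7 were higher in pSHF and 8 neither in both comparisons, with medians of 1.93 and 2.55 (percentile 100 in both). The potassium channel gene KCNA5 stood at 48.2 CPM in pSHF, 3.32 CPM in FHF and 2.16 CPM in aSHF. Of 10 sinoatrial node genes, 6 were higher and 1, KCNJ5, lower in pSHF than in FHF (median 2.43, percentile 100), and 7 were higher and 2 lower than in aSHF (median 2.69, percentile 100). ISL1 was 126-fold (78.5 to 217) and 204-fold (111 to 426) higher. The endoderm list had medians of 2.98 and 2.89 (percentile 100 in both, 2.98 and 2.89 with undetected members at their bounds), beside an endoderm-like share of 3.35% in pSHF. The extracellular matrix list had medians of 2.66 and 3.19 (percentile 100 in both), with DCN 107-fold higher than in FHF (53.8 to 248), beside a fibroblast-like share of 13.9%. The vascular list had medians of 2.08 and 2.41 (percentile 100 in both), beside an endothelial-like share of 6.03%, with PECAM1 11.4-fold (8.94 to 14.7) and 7.66-fold (6.22 to 9.52) higher. BMP response genes had a median of -1.06 against FHF (percentile 0), with 6 of 13 lower in pSHF.

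Within the cardiomyocyte-like cells the atrial and nodal difference was also seen. SHOX2 was 807-fold higher in pSHF than in FHF (542 to 1261), at 505 and 0.626 CPM, NR2F2 62.9-fold (56.0 to 70.9), ISL1 173-fold (106 to 304) and NPPA 38.2-fold (37.0 to 39.5). MYL2 was 395-fold lower (303 to 526), IRX4 529.9-fold lower (243 to 1444) and HEY2, with 3 UMIs in pSHF, had a ratio of 719 (246 to 3490). Of 6364 genes, 721 differed, 263 higher in pSHF and 458 in FHF. The split was 347 and 340 with TMM, which shifted all log2 ratios by 0.16, and 372 and 317 with the median of ratios, which shifted them by 0.20. With the stricter cell filter it was 338 and 352. Against aSHF, 835 of 6323 genes differed, 252 higher in pSHF and 583 in aSHF, with 327 and 435 under TMM (shift 0.18) and 342 and 418 under the median of ratios (shift 0.21), and 365 and 458 with the stricter cell filter.

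Other large ratios in these pSHF cells over FHF were those of NTM (330.2-fold, 159.8 to 823), MYBPHL, an atrial myosin binding protein gene (225-fold, 118 to 493), LIMCH1 (204-fold, 143 to 303), LRRTM3 (116-fold, 75.5 to 188), MYH11 (56.8-fold, 45.5 to 71.8) and NR2F1 (51.4-fold, 43.3 to 61.5). In FHF they were those of MOXD1 (192-fold, 104 to 400.1), SCUBE3 (118-fold, 70.2 to 216), LAMB1 (118-fold, 73.8 to 203), PDGFD (78.3-fold, 52.5 to 122), LAMA4 (58.6-fold, 44.4 to 79.1) and FBN2 (48.6-fold, 43.1 to 55.1). Against aSHF, SHOX2 had 1 UMI in aSHF and a ratio of 18512 (3322 to 731270), NR2F1 was 442-fold (268 to 790.4), NR2F2 186-fold (152 to 230.4), ISL1 331-fold (168 to 769), VSNL1 57.9-fold (46.8 to 72.5) and SHD 59.2-fold (45.8 to 77.8) higher in pSHF. MYL2 was 619.8-fold lower (475 to 825), MOXD1 465-fold lower (253 to 969) and IRX4 288-fold lower (132 to 785), and PRDM16, with 2 UMIs in pSHF, had a ratio of 457 (126 to 3781).

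Of 10 ventricular genes, 5 were higher in FHF than in pSHF cardiomyocyte-like cells and 5 neither (median -2.29, percentile 0), and 7 were higher in aSHF and 3 neither (median -2.59, percentile 0). Of 14 atrial genes, 7 were higher in pSHF than in FHF (median 1.79, percentile 100) and 10 were higher than in aSHF (median 2.22, percentile 100). Of 10 sinoatrial node genes, 6 were higher than in FHF (median 2.62, percentile 100), while 7 were higher and 2, TBX3 and KCNJ5, lower than in aSHF (median 2.80, percentile 100). The sarcomere list stood at -0.03 and 0.04, with TNNI3, the mature troponin I gene, 9.87-fold (9.55 to 10.2) and 14.9-fold (14.3 to 15.5) higher in pSHF. Many sarcomere genes are among the markers that named these cells, so medians near 0 were partly set by that choice. The TNNI3 value is uncertain, since 24.4% of its exons overlap another gene. The medians of the atrioventricular canal list (-0.51), extracellular matrix list (-1.28) and epicardial list (-1.29) against FHF had the opposite sign under other settings.

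The comparisons of successive stages asked how the libraries of each lineage differed with time. From day 3 to day 4, most streak genes were lower and some vascular genes higher in both protocols: all 9 primitive streak genes were lower in FHF (median -4.45, percentile 0) and 7 of 11 in SHF (median -3.28, percentile 0). CER1 was 1562-fold lower in FHF (1197 to 2080) and 119.6-fold lower in SHF (98.9 to 146), and TBXT 254-fold lower in SHF (156 to 445). MIXL1 was 141-fold (119 to 168) and 48.7-fold (44.5 to 53.4) lower, FGF17 99.1-fold (84.1 to 117) and 26.2-fold (23.7 to 29.1) lower, and LZTS1 321-fold (210.0 to 519) and 29.4-fold (25.7 to 33.8) lower. In FHF the collagen gene COL2A1 was 245-fold (179 to 347), CXCL14 84.2-fold (56.4 to 132), TFPI 55.1-fold (44.1 to 69.9) and TMEM88 42.9-fold (39.8 to 46.3) higher at day 4; IGF2 was 145-fold higher, an uncertain value since 73.7% of its exons overlap another gene. In SHF the endothelial gene CD34 was 223-fold higher (137 to 390.0), SYT10 74.3-fold (60.4 to 92.5) and SOST 60.9-fold (50.3 to 74.5). PLVAP had 2 and CDH5 1 UMI at day 3, ratios of 2533 (701 to 20920) and 3650 (655 to 144217). The vascular list had medians of 3.21 in FHF and 3.93 in SHF (percentile 100 in both), with 4 of 11 and 7 of 11 members counted as higher. In FHF 640 genes differed, 378 higher at day 4 and 262 at day 3, and in SHF 431, 270 and 161. TMM shifted the FHF log2 ratios by -0.12 and the median of ratios by -0.14, with which the split was 325 and 332.

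From day 4 to day 6, contractile genes were higher in the FHF library: 15 of 16 sarcomere genes were higher (median 4.29, percentile 100), with MYH6 3358-fold (2174 to 5498) and TNNT2 186-fold (172 to 201) higher, the smooth muscle actin gene ACTA2 280.2-fold (215 to 373), and PLN with 1 UMI at day 4. CHGA was 44.6-fold (35.1 to 57.4) and LINC00458 48.5-fold (42.4 to 55.8) lower. From SHF at day 4 to aSHF at day 6, where the Cell Ranger version changed along with stage and treatment, HAND2, a second heart field factor, was 26.2-fold (23.2 to 29.6), NKX2-5 12.6-fold (11.1 to 14.4) and MYH6 11.7-fold (10.4 to 13.2) higher, and the Nodal target LEFTY2 was 55.3-fold (46.3 to 66.7) and CRABP1 32.7-fold (26.0 to 41.7) lower. From SHF at day 4 to pSHF at day 6, NR2F1 was 63.3-fold (59.6 to 67.3), NR2F2 56.5-fold (52.7 to 60.6), TGFB2 92.0-fold (77.1 to 111) and IGFBP5 80.1-fold (71.1 to 90.6) higher. LEFTY2 was 1085-fold (465 to 3341) and the pluripotency gene POU5F1 40.5-fold (35.0 to 47.3) lower. The anterior second heart field list had a median of 1.75 in aSHF (6 of 10 higher, 1 lower, percentile 100) and the posterior list one of 2.63 in pSHF (4 of 12 higher, percentile 100). FHF differed in 644 genes, 416 higher at day 6 and 228 at day 4, aSHF in 392, 260 and 132, and pSHF in 535, 330 and 205. TMM and the median of ratios shifted log2 ratios by -0.12 and -0.15 in aSHF, with splits of 202 and 188 and of 185 and 198. They shifted them by -0.18 and -0.19 in pSHF, with splits of 230 and 303 and of 224 and 312.

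From day 6 to day 20, most sarcomere and calcium handling genes were higher in each lineage, and most cell cycle genes were lower. The sarcomere medians were 1.76 in FHF (12 of 18 higher), 5.27 in aSHF (18 of 18) and 6.28 in pSHF (16 of 17), each at percentile 100. The calcium handling medians were 1.83 (10 of 10 higher), 4.09 (10 of 10) and 4.08 (9 of 12), each at percentile 100. MYL2 was at least 26128-fold higher in aSHF and had 1 UMI in FHF at day 6, a ratio of 51843 (9304 to 2047730). The myoglobin gene MB was 5401-fold higher in aSHF (3533 to 8725), the creatine kinase gene CKM 16438-fold (7552 to 44794) and NPPA 7106-fold (4235 to 12999) in pSHF, and IRX4 553-fold (329 to 1012) in FHF. LIN28A, an RNA-binding protein gene of early embryonic cells, was at least 1852-fold lower in FHF and at least 3277-fold lower in aSHF. LIN28A had 1 UMI in pSHF at day 20, a ratio of 4470 (802 to 176585). HAS2 was 319-fold (234 to 447) and HAPLN1 162-fold (139 to 189.5) lower in aSHF, and HOXB1 299.8-fold (196 to 485) and FOXH1 119.5-fold (87.3 to 168) lower in pSHF. The cell cycle list had medians of -1.14 (8 of 15 lower), -2.13 (15 of 16) and -2.32 (15 of 15), each at percentile 0. FHF differed in 1818 genes, 1009 higher at day 20 and 809 at day 6, aSHF in 2529, 1314 and 1215, and pSHF in 2225, 1023 and 1202. With no minimum CPM the FHF split was 1823 and 2078 and the aSHF split 2434 and 2752, and the aSHF split was 1244 and 1901 without mitochondrial and ribosomal protein genes. TMM and the median of ratios shifted the pSHF log2 ratios by 0.14 and 0.13, with splits of 1178 and 945 and of 1169 and 957; with the stricter cell filter the pSHF split was 1065 and 823.

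Differences at day 6 recurred in part at day 20. Between pSHF and FHF, 57 genes were higher in FHF on both days, against 10.5 for independent lists, and 47 were higher in pSHF on both days, against 5.43. Between pSHF and aSHF the numbers were 49 against 7.79 in pSHF and 49 against 7.93 in aSHF. Between aSHF and FHF they were 15 against 1.25 in aSHF and 13 against 3.602 in FHF. In the pairs with aSHF, the Cell Ranger version was confounded with lineage on both days, so part of the recurrence may come from the software. The 15 genes include RPS10, RPL36A and NDUFA7, whose exons overlap another gene. Some genes higher at day 6 were higher in the other library of the pair at day 20. Between pSHF and FHF these were 35 of FHF and 14 of pSHF. Between pSHF and aSHF they were 25 of pSHF and 34 of aSHF, and between aSHF and FHF 1 of aSHF and 11 of FHF. No value for independent lists was computed for these opposite directions. An excess particular to the same direction is therefore not shown. From day 4 to day 6, 21 genes were higher in FHF than in SHF and then than in pSHF, against 1.15 for independent lists, and 3 turned to the opposite direction. In the other day 4 to day 6 overlaps the opposite direction held more genes: 6 were higher in FHF than in SHF and then than in aSHF, with 9 opposite, 4 were higher in SHF and then in aSHF, with 10 opposite, and 9 were higher in SHF and then in pSHF, with 10 opposite. From day 3 to day 6, 10 genes were higher in FHF than in SHF and then than in aSHF, with 12 opposite, and 17 then than in pSHF, with 11 opposite. In SHF and then aSHF 15 were higher, with 6 opposite, and in SHF and then pSHF 10, with 13 opposite.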

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

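The tests of explanations in this part were all chosen after the results they concern had been seen; the medians themselves belong to comparisons fixed in advance. Each value below is a list median whose sign was opposite in another lineage over the same days, by at least 0.5 on the log2 scale in both directions. Percentiles of these opposite medians, where not printed, were at most 0.71 or at least 98.95. Counts of members need 20 CPM in the higher library, so members below that level were not counted at any fold. With 1 library per lineage and day, none of these differences between lineages was tested.

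Between day 4 and day 6, the HOX list had medians of -0.63 in aSHF (1 of 6 members at least 2-fold higher, 1 lower) and 2.49 in pSHF (5 of 9 higher), each against SHF at day 4. The sarcomere list stood at 4.29 in FHF (15 of 16 higher) and 1.23 in aSHF (7 of 13 higher, 1 lower) but at -1.69 in pSHF (5 of 11 lower, 3 higher). The ventricular list stood at 0.75 in aSHF (2 of 6 higher) and -0.98 in pSHF (2 of 7 lower, 1 higher). The WNT response list had medians of -0.69 in FHF (percentile 1.4), where none of 5 members was counted as different, and 0.50 in aSHF (1 of 6 higher, percentile 92.7). The immediate early and heat shock list had medians of 0.55 in FHF (3 of 12 higher), 1.04 in pSHF (5 of 12 higher) and -0.50 in aSHF (2 of 12 lower). The endoderm list had medians of 0.54 in FHF (3 of 12 higher, 1 lower), -1.08 in aSHF (2 of 8 lower, 1 higher) and -1.03 in pSHF (1 of 8 lower). In the aSHF values of this paragraph the Cell Ranger version is confounded with stage and treatment.

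Between day 6 and day 20, the endoderm list had medians of -3.05 in FHF (6 of 11 members at least 2-fold lower), -2.41 in aSHF (3 of 6 lower, 1 higher) and 2.79 in pSHF (5 of 12 higher, 2 lower). The amnion and surface ectoderm list had medians of -2.45 in aSHF (1 of 4 lower) and 1.84 in pSHF (1 of 6 higher). The neural list had medians of 1.83 in FHF (1 of 3 higher), 2.47 in pSHF (2 of 4 higher) and -1.12 in aSHF (2 of 4 higher, 1 lower). Their percentiles were 98.8, 99.85 and 4.88. The FHF value turned to -0.21 without mitochondrial and ribosomal protein genes in the totals. A signal outside the kept cells was the 19.4% of pSHF barcodes at day 20 that exceeded 30% mitochondrial UMIs and entered no comparison except under the setting with no filter on cells.

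The median of the retinoid response list lay lower in aSHF than in pSHF at day 6, where 3 of 8 members were at least 2-fold higher in pSHF and 5 were neither, although per the labels both cultures received retinol; whether the aSHF label is complete and correct was not tested. An exchange of the labels of these libraries is argued against by the anterior second heart field list, whose median for pSHF minus aSHF was -1.46. The median of the retinoid response list for aSHF at day 6 minus SHF at day 4 was -0.30, against 1.03 for pSHF. As a set the list was not higher in aSHF, so that library may not have responded to retinol by day 6. No second heart field library without retinol was made at day 6, so differences from day 4 hold stage as well as treatment. Of the members at least 2-fold from FHF in the same direction in aSHF and pSHF at day 6, RARB was higher and TGM2 lower. RARB was already higher in SHF than in FHF at day 4, before the retinol window. Single members therefore do not settle the question. The Cell Ranger version differed between aSHF and SHF but not between pSHF and SHF. Whether BMP4 given with retinol opposed the response cannot be told apart from other differences between the cultures: the BMP response list stood at -1.36 for pSHF minus aSHF, but no library received BMP4 without retinol in that window. A difference between the lineages themselves also stays open.

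Some genes were higher in aSHF than in both FHF and pSHF on both day 6 and day 20. Of 529 genes whose exons overlap another gene, 3.02% were at least 0.5 log2 higher, against 0.503% of 5169 other genes, a ratio of 6.01; with FHF or pSHF in the place of aSHF the ratio was 0 or 0.902. For overlapping genes, such as RPS10, RPL36A and NDUFA7, the other Cell Ranger version of the aSHF files may therefore be the source. Another 4 genes without an overlap were at least 2-fold higher on both days, with smallest ratios of CPM + 1 of 2.45 for IRX2, 2.60 for MID1IP1, 2.13 for PDLIM1 and 3.23 for CCBE1. The counting of overlapping genes cannot act on them by definition, so they do not test the software explanation. These 7 genes were chosen after their values were seen, and other effects of the software version stay open, since lineage and version are confounded in comparisons of aSHF with FHF or pSHF.

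Among the genes at least 2-fold higher in pSHF than in FHF at day 20 were members of the endoderm list as well as of the atrial, sinoatrial node and extracellular matrix lists. Endoderm-like cells held 53.6% of the UMIs of EPCAM, the lowest of 5 endoderm members, with 31.2% in cardiomyocyte-like cells and 7.09% in cluster 10. They held 99.3% of those of AFP, 98.7% of TTR, 98.6% of APOA2 and 94.8% of APOA1. These 5 genes are among the markers that named the endoderm-like cells, so the shares do not decide where the RNA came from. The same cells are argued against as the source of 19 atrial, sinoatrial node and matrix members, where they held at most 11.5% (FN1). Cardiomyocyte-like cells held 82.9% of the SHOX2 and 97.3% of the NPPA UMIs. NPPA is among the markers that named these cells, and both genes were among the 10 leading genes of cluster 7. These 2 shares therefore do not decide where the RNA came from. Whether endoderm-like cells came from the pSHF treatment or from this culture alone was not tested.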

How the results depend on the processing

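Of the alternatives, 3 were chosen after the data were seen: cluster 10 counted as cardiomyocyte-like, overlapping genes left out, and cells of other types left out. Of 231 recomputed counts of genes, 193 stayed within 1.5 times the reported count, and all 38 that did not came from the minimum level, which by construction changes how many genes can be counted. With no minimum CPM the counts were 884 at day 3, 362 at day 4, 1193, 1510 and 1580 at day 6 (aSHF against FHF, pSHF against FHF, pSHF against aSHF) and 741, 2199 and 2444 at day 20. In cardiomyocyte-like cells they were 728, 1807 and 2015. For stages they were 1818, 1591 and 3901 in FHF, 1318 in SHF, 977 and 1568 from day 4 to aSHF and pSHF at day 6, and 5186 and 4679 from day 6 to day 20. With a minimum of 50 CPM they were, in the same order, 131, 44, 274, 322, 328, 140, 392 and 469, then 138, 390 and 478, then 325, 351, 1027, 199, 209, 241, 1448 and 1206. At that minimum the genes shared by day 3 and day 4 were 8 in FHF and 2 in SHF; under TMM scaling both numbers stayed within 1.5 times those reported. Counts in one direction stayed within 1.5 times for 379 of 462.

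Of 2609 list medians, 2362 moved by at most 0.25, 238 by more, and 9 that had stood at least 0.5 from 0 changed sign, for which the cause was not tested. With totals that left out mitochondrial and ribosomal protein genes, the posterior second heart field list for aSHF against FHF at day 6 was 0.77, the epicardial list in cardiomyocyte-like cells 0.89 (pSHF against FHF) and 1.05 (pSHF against aSHF), and the neural list for FHF at day 20 against day 6 -0.21. With the stricter cell filter, the values for pSHF against FHF in cardiomyocyte-like cells were 0.21 for the atrioventricular canal list, 1.94 for extracellular matrix and 1.21 for epicardial genes, and against aSHF 2.71 for extracellular matrix and 1.36 for epicardial genes. FN1 had a log2 ratio of 0.019 against FHF under that filter, the 1 ratio of 2-fold or more that changed sign among 16038 recomputed gene ratios; 6865 moved beyond their counting interval and 9172 did not.

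Of 162 shares of cells, 114 stayed within their interval and 48 did not; the cause was not tested. The cardiomyocyte-like share of pSHF at day 20 was 67.3% at resolution 0.25, 54.2% at resolution 1.0, 71.4% with no cell filter, 48.0% with the stricter filter and 54.5% with predicted doublets kept. The FHF share was 98.7% with no filter and 93.5% with the stricter one, and the aSHF share 97.5% with the stricter one. The endothelial-like share at day 4 was 0% in FHF and 0% in SHF at resolution 1.0, and 18.9% in SHF with predicted doublets kept. The self-test found all 2.5-fold changes in its 3 comparisons. It changed only genes that reached 20 CPM in the pooled libraries and held counting error alone, so it says little about limits of depth. Genes with fewer than about 3 UMIs have wide intervals or bounds.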

Other observations

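The genes of the last paragraph were singled out after their values were seen; the lists were fixed in advance, and no further explanation was tested in this part.

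The aSHF and FHF cardiomyocyte libraries of day 20 differed in some metabolic and stress genes, while most members of these lists were not counted as different. Of 14 glycolysis and hypoxia genes, 2 were at least 2-fold higher in aSHF and 12 neither (median 0.74, percentile 100). EGLN3, an oxygen-sensing hydroxylase gene, stood at 122 CPM in aSHF and 47.2 CPM in FHF, and the glucose transporter gene SLC2A1 at 229 and 107 CPM. Of 15 genes of fatty acid and oxidative metabolism, 3 were higher in aSHF and 12 neither (median 0.19, percentile 92.7). COX7A1, a subunit of cytochrome oxidase in muscle, was 3.61-fold higher (3.44 to 3.79) and PDK4, which restrains glucose oxidation, 3.55-fold higher (3.29 to 3.84). In pSHF cardiomyocyte-like cells COX7A1 was 5.72-fold higher than in FHF (5.46 to 6.01), whereas PDK4 was 2.36-fold lower (2.02 to 2.77). Immediate early and heat shock genes had a median of 0.79 in aSHF against FHF (percentile 100), with 4 of 13 higher. Among them ATF3 stood at 376 and 98.0 CPM and FOS at 343 and 169.8 CPM; HSPA1A and HSPA1B are near-identical copies, so their values are uncertain.

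At day 6 the immediate early genes parted pSHF from aSHF. Of 12 list members, 6 were at least 2-fold higher in pSHF and 6 neither (median 1.09, percentile 100). FOSB stood at 76.6 and 2.16 CPM, 35.6-fold higher (29.4 to 43.3), EGR1 was 32.4-fold higher (26.7 to 39.7) and FOS 23.1-fold higher (20.5 to 26.2). The difference was not particular to pSHF, since FOSB was also higher in FHF than in aSHF at day 6. From day 4 to day 6 the immediate early and heat shock list had medians of 0.55 in FHF, 1.04 in pSHF and -0.50 in aSHF. Such genes respond within minutes to handling and dissociation, and the labels give no times for these steps. The cell cycle list had a median of 0.32 (percentile 96.7), with MKI67 2.55-fold (2.46 to 2.64) and TOP2A 2.10-fold (2.05 to 2.15) higher in pSHF.

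In pSHF, 26 genes with no exon overlap were at least 2-fold higher than in both FHF and aSHF on both day 6 and day 20. The smallest of the 4 ratios of CPM + 1 was 31.3 for NR2F1, 20.9 for NR2F2, 12.2 for NR2F2-AS1, 6.44 for DLK1, 4.98 for LIMCH1, 4.63 for GPC3 and 4.10 for TLE1. The cells that held these transcripts at day 20 differed in part. Cardiomyocyte-like cells, which held 21968331 of the 34468064 kept pSHF UMIs, held 76.9% of the NR2F2 UMIs (76.2 to 77.6) and 68.8% of those of NR2F1 (67.5 to 70.0). Fibroblast-like cells held 88.7% of the DLK1 UMIs (88.2 to 89.2) and 16.1% of those of NR2F1 (15.2 to 17.1). Scaled to the UMIs of each class, NR2F1 was not particular to cardiomyocyte-like cells. It stood at 181 CPM there, 280 CPM in fibroblast-like and 149 CPM in endothelial-like cells. In the same order, NR2F2 stood at 477, 262 and 448 CPM and DLK1 at 8.33, 4076 and 5.03 CPM. In FHF 1 such gene was found, FERMT1, with a smallest ratio of CPM + 1 of 2.16.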
